A study of Homo sapiens with 8 samples.

How the data were processed

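Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map BRD2 and histone H4 acetylated at lysines 5 and 8 (H4K5acK8ac) in NCI-H23, an established human non-small cell lung cancer line. Cells were treated for 24 h with 500 nM JQ1, an inhibitor of the bromodomains of the BET protein family to which BRD2 belongs, or with the solvent DMSO. Per the labels' protocols, fly chromatin and an antibody to the fly histone H2Av were added as a spike-in. The labels gave 4 groups, BRD2 under DMSO, BRD2 under JQ1, H4K5acK8ac under DMSO and H4K5acK8ac under JQ1, with 2 replicates each. The treatment label of the BRD2 DMSO samples held a misprint in the unit of time, and the 24 h of the protocol was used. Nothing in the labels says that the replicates came from separate cultures, so p-values over samples measure only the spread between these samples, which may be technical.

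The deposited files were 8 peak lists, 1 per replicate, with no pooling of replicates. The submitters' processing notes name Bowtie, SAMtools and MACS2, without versions, and the builds hg19 and dm3. Narrow peaks were deposited for BRD2 and broad peaks for H4K5acK8ac. Each deposited peak carries a fold enrichment, which is a linear ratio, and values of −log10 p and −log10 q, all per the column layout of the deposited lists. The deposited score column is 10 times the −log10 q, truncated to a whole number, and was not used. A further deposited column of other content, the summit offset of the BRD2 peaks, was not used either. The lowest −log10 q in the 8 lists lay between 4.31 and 4.43, just above 4.30, which corresponds to q = 5e-05. The use of a control library, and whether the spike-in scaled the signal before peaks were called, are not given in the sources used here. Peak lists hold no reads, so the sequencing depth is unknown and no read count, signal level or spike-in ratio could be compared. A shift in signal over the whole genome can be seen in such lists only through which peaks passed the threshold. The authors' fold enrichment and −log10 p were used only to rank or filter peaks within a list.

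Peaks of the 2 lists of a group were merged where they overlapped by at least 1 bp, and a merged region held by both lists was called reproducible. A reproducible DMSO region was called retained where both JQ1 lists overlapped it by at least 1 bp, partial where 1 did and lost where neither did. A reproducible JQ1 region was called gained where neither DMSO list overlapped it. "Lost" and "gained" therefore describe peak calls. Strength was the percentile rank of a region's fold enrichment within its list, averaged over the 2 lists. Where a region held several peaks of a list, the highest rank among them was taken, so such regions can rank higher by construction. Peak numbers and covered lengths were compared with a two-sided exact permutation test, for which 2 samples against 2 give 6 assignments and a smallest p of 0.333. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error over regions only. Chance overlap was taken from 100 seeded shuffles of the regions within their chromosomes. Shares were compared with Fisher's exact test, two-sided, with 1e-300 as the smallest p written. Median strengths were compared with a two-sided permutation test of 100000 resamples, whose smallest p is 1e-05. Regions of one genome are not independent replicates, so the p-values over regions describe these lists. Benjamini-Hochberg adjustment was applied over width quintiles and over chromosome bands.

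The definitions of region states, the tests and most alternative settings were fixed before the data were examined. The named regions follow a rule fixed then: per antibody, the 5 lost and 5 retained regions of highest mean rank under DMSO and the 5 gained regions of highest mean rank under JQ1. The same plan held 14 gene lists, a promoter share and named genes by promoter. These were not run, because the annotation at hand, GRCh38.p14, is of another build than the hg19 coordinates of the lists. Regions are therefore given by hg19 coordinates, counted from 1, and by hg19 chromosome band, from the band table of circlize 0.4.16, with chromosome lengths from GenomeInfoDb 1.38.1. What genes lie in them was not analysed here. After the data were examined, a centromeric zone was defined as everything within 2 Mb of a centromeric, variable or stalk band, 345 Mb or 11.1% of the genome. All values by zone, by band, by staining class or by class or quintile of strength, the comparison of BRD2 retention by acetylation with its alternatives, and the alternatives for H4K5acK8ac at lost BRD2 regions under JQ1, were added at that point.

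Alternatives were a stricter fold enrichment (at least 5) or −log10 p (at least 6, then 20), autosomes only, merging of peaks within 1 kb, an overlap of at least 50%, retention in either JQ1 list, lists of matched length, the replicate number as a block, leaving out each replicate, and restriction to regions outside the centromeric zone or to BRD2 peaks of at least 210 bp. Leaving out a list made every peak of the other list of its group count as reproducible. With a JQ1 list left out, retention needed only the other JQ1 list. These settings thus change the definition of a region or its state along with the replicate. The code for region states was run on simulated lists, in which all 1000 retained and all 4000 lost regions out of 5000 were recovered. The simulated replicates were identical, and retained peaks had the same bounds under both treatments. Full recovery was therefore fixed, and it checks the code, not state calls in lists that differ in peak width. For the permutation test of median strength, 4.5% of 200 random splits of unchanged regions fell below a p of 0.05. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and interval operations were checked against bedtools 2.31.1.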

Results

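BRD2 and H4K5acK8ac were mapped by ChIP-seq in NCI-H23 lung cancer cells after 24 h with 500 nM JQ1 or with DMSO, in 2 replicates per group. BRD2 is a chromatin protein that binds acetylated histones through a pair of bromodomains, and JQ1 occupies the acetyl-lysine pocket of these domains. The BRD2 lists held 7499 and 7594 peaks under DMSO and 1413 and 1608 under JQ1. The H4K5acK8ac lists held 32265 and 33659 peaks under DMSO and 27437 and 30104 under JQ1. Read depth was unknown for all 8 lists. The narrowest BRD2 peaks were 196 and 209 bp wide under DMSO and 48 bp in both JQ1 lists, so the shortest peak that could be called differed between the BRD2 groups. For H4K5acK8ac the narrowest peaks were 227 to 248 bp wide in the 4 lists.

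The first comparison asked how BRD2 occupancy differed between JQ1 and DMSO. BRD2 peaks numbered 7546.5 ± 67.2 (SD, n = 2) under DMSO and 1510.5 ± 138 (SD, n = 2) under JQ1, which is 4.996-fold fewer, or −2.32 on the log2 scale. They covered 3466 ± 87.3 kb under DMSO and 267.05 ± 34.1 kb under JQ1, 13.0-fold less. Because the shortest width called differed between the groups, these lengths were not measured on one scale. A minimum width of 210 bp, which by construction removed mostly JQ1 peaks (1128 of 1413 and 1286 of 1608, against 737 of 7499 and 428 of 7594 under DMSO), gave a log2 ratio of −4.52 for number, and a −log10 p of at least 20 gave −1.28. Of 5394 reproducible BRD2 regions under DMSO, 5077 were lost under JQ1 (94.1%, 95% interval 93.5 to 94.7), 8 were found in 1 JQ1 list and 309 were retained (5.73%, 5.12 to 6.38), or 9.39% with matched numbers of peaks. Per DMSO list, the retained share of peaks was 5.61% ± 1.01 (SD, n = 2). Both JQ1 lists lay below both DMSO lists in number and in length, and the exact permutation test gave p = 0.333 for each, the smallest value that 2 against 2 samples allow. Shuffled regions overlapped both JQ1 lists in 0.019% of cases.

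**Figure D1:**
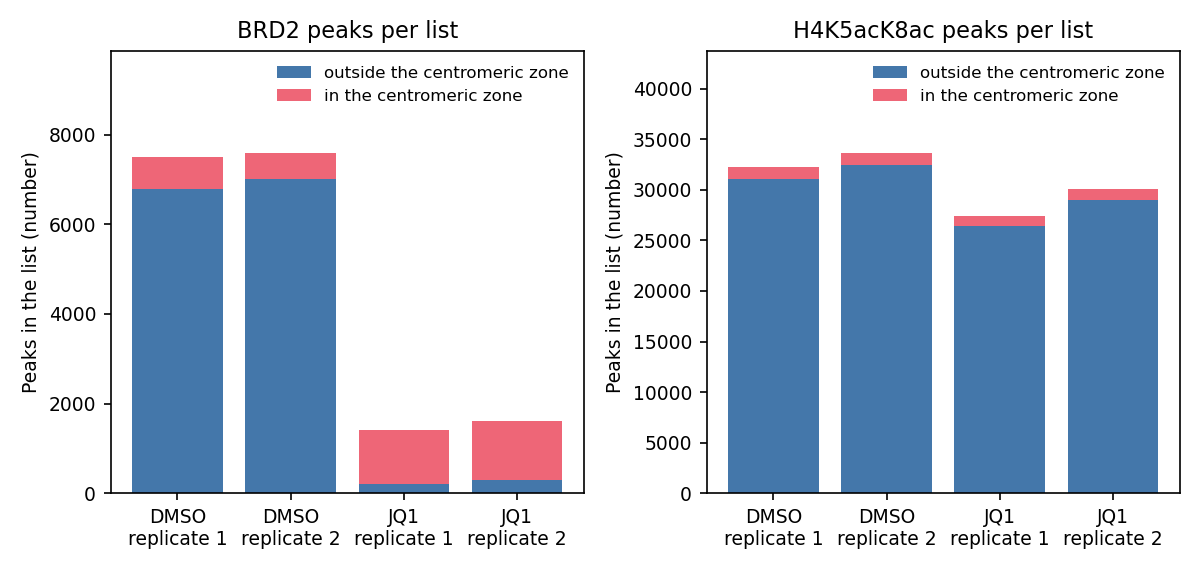
Number of peaks in each of the 8 lists, for BRD2 (left) and H4K5acK8ac (right), with bars split into peaks outside and inside the centromeric zone. The BRD2 lists fall from 7499 and 7594 peaks under DMSO to 1413 and 1608 under JQ1, of which 85.7% and 82.2% lie in the zone.

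The remaining BRD2 peaks lay mostly next to centromeres. The centromeric zone held 9.60% and 7.60% of the BRD2 peaks under DMSO and 85.7% and 82.2% under JQ1, against 11.1% of the genome. Outside the zone, BRD2 peaks numbered 6898 ± 168 (SD, n = 2) under DMSO and 244 ± 59.4 (SD, n = 2) under JQ1, 28.3-fold fewer. There, 88 of 4970 reproducible regions were retained (1.77%, 1.42 to 2.18), while 221 of 424 were retained inside the zone (52.1%, 47.2 to 57.0). The retained shares differed by 50.4 percentage points (Fisher's exact test, p = 2.14e-196). The zone was defined after these lists were examined, so the p-value describes the lists and is not an independent test. JQ1 peaks were narrow, with median widths of 86 and 83 bp in the 2 lists, against 554.5 bp for the retained zone regions under DMSO, so that settings tied to width lower retention by construction. With at least 50% of the DMSO region overlapped, 38 of 424 zone regions (8.96%) and 3 of 4970 others (0.0604%) were retained, and among peaks of at least 210 bp 60 of 395 (15.2%) and 6 of 4575 (0.131%). Inside the zone the number of BRD2 peaks was 648.5 ± 101.1 (SD, n = 2) under DMSO and 1266.5 ± 78.5 (SD, n = 2) under JQ1, yet the covered length was 506.85 ± 90.1 kb and 245.3 ± 25.2 kb. The median widths of zone peaks were 386.5 and 384 bp under DMSO and 97 and 92 bp under JQ1, so a minimum of 210 bp removed mostly JQ1 peaks and left 598 ± 60.8 (SD, n = 2) under DMSO and 288 ± 12.7 (SD, n = 2) under JQ1. Merging peaks within 1 kb left 389 ± 19.8 and 295 ± 26.9. The 221 retained zone regions held 746 separate JQ1 regions, 3.38 each on average. Bands 4p11, 2p11.1, 10q11.21, Xq11.1 and 5q11.1 together held 523 of the 1181 reproducible BRD2 regions under JQ1 (44.3%).

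**Figure D2:**
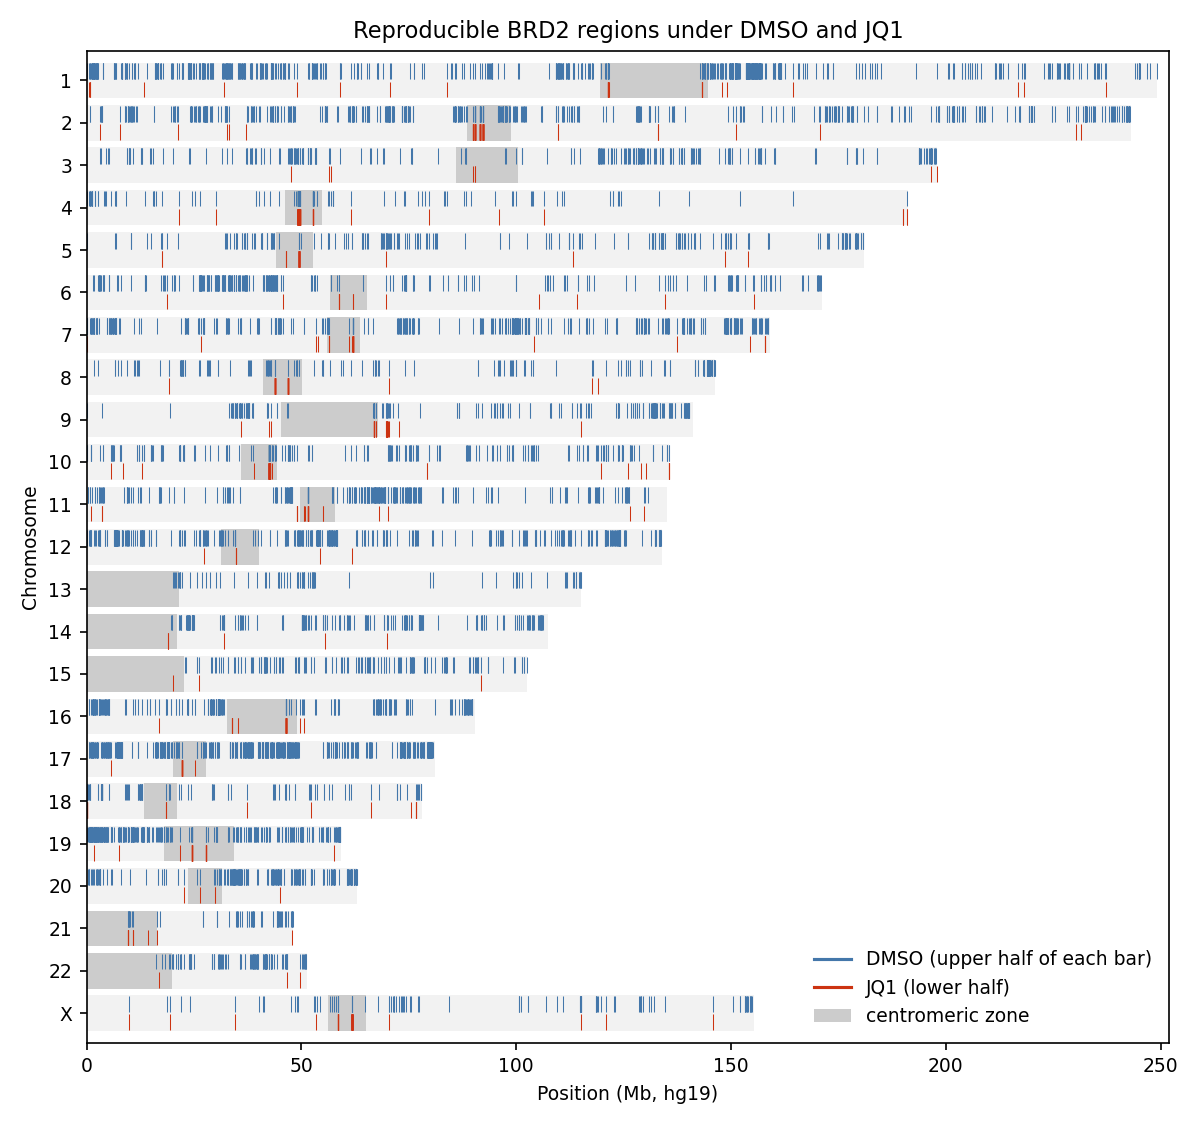
Positions of the reproducible BRD2 regions on chromosomes 1 to 22 and X of hg19, in Mb, with 1 line per region; DMSO regions fill the upper part of each bar, JQ1 regions the lower part, and the centromeric zone is shaded. Regions on chromosome Y are not drawn. DMSO regions are spread along the arms, and 1009 of all 1181 JQ1 regions lie in the zone.

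Among bands of at least 1 Mb outside the centromeric zone, those densest in BRD2 under DMSO kept almost none of it. Band 1q22 held 29 regions, or 19.3 per Mb, and none was retained. Band 19p13.3 held 81 regions and kept 1. None was retained among 55 regions of 1q21.3, 38 of 17q21.31 and 54 of 17q25.3. Bands inside or next to the zone were mixed: 4p11 (23.2 per Mb) kept 44 of 51 regions, 1p11.2 kept 7 of 11 and 10q11.21 kept 30 of 36, while 1q21.1 kept 4 of 25, 2q11.2 kept 0 of 28 and 2q11.1 kept 0 of 9. The strongest lost region lay at chromosome 2, 3622246 to 3623641 (2p25.3), with fold enrichments of 45.9 and 57.5 in the DMSO lists. Next came chromosome 5, 133968435 to 133969039 (5q31.1; 41.5 and 45.4), chromosome 16, 70557589 to 70558276 (16q22.1; 40.1 and 44.7), chromosome 1, 110026508 to 110027307 (1p13.3; 28.9 and 41.0) and chromosome 6, 76311203 to 76312650 (6q14.1; 26.8 and 53.0). All 5 were called in H4K5acK8ac under both DMSO and JQ1.

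The strongest retained BRD2 region lay outside the zone, at chromosome X, 19470045 to 19470617 (Xp22.12), with fold enrichments of 87.8 and 90.1 under DMSO. The next were at chromosome 9, 66970865 to 66971795 (9q13; 75.02 and 73.6), chromosome 11, 51588685 to 51589359 (11p11.12; 69.8 and 58.5), chromosome 9, 69710564 to 69711468 (9q21.11; 51.9 and 51.6) and chromosome 2, 92305916 to 92326299 (2p11.1; 40.3 and 47.5). The 9q13, 11p11.12 and 2p11.1 regions lay in the zone. Gained BRD2 regions numbered 138 of 1181 (11.7%, 9.91 to 13.7), with a median width of 53 bp. The 5 strongest gained regions lay in Yq11.21, which held 3, in 5p11 and, outside the zone, in 4q21.21 at chromosome 4, 79750948 to 79751002. None of them was in H4K5acK8ac.

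Retention of BRD2 regions did not follow strength under DMSO in one direction. The median percentile of fold enrichment was 61.3 for retained and 56.8 for lost regions (permutation test, p = 0.0331). The difference of 4.57 was 0 without BRD2 DMSO replicate 1, 14.2 without BRD2 DMSO replicate 2 and 14.1 with strength taken from −log10 p. Without 1 DMSO list, peaks found only in the other DMSO list were counted as regions too. Over all regions, retention was highest in the weakest of 10 classes of strength, with 72 of 540 (13.3%), and was 8.16% in the strongest; in the zone the weakest class kept 38 of 43 (88.4%). Outside the zone the medians were 76.8 and 56.6 (permutation test, p = 1e-05, the smallest possible), and inside it 53.5 and 59.1 (permutation test, p = 0.241). Even among the strongest 10% of regions outside the zone, 18 of 497 were retained (3.62%, 2.16 to 5.66).

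**Figure D3:**
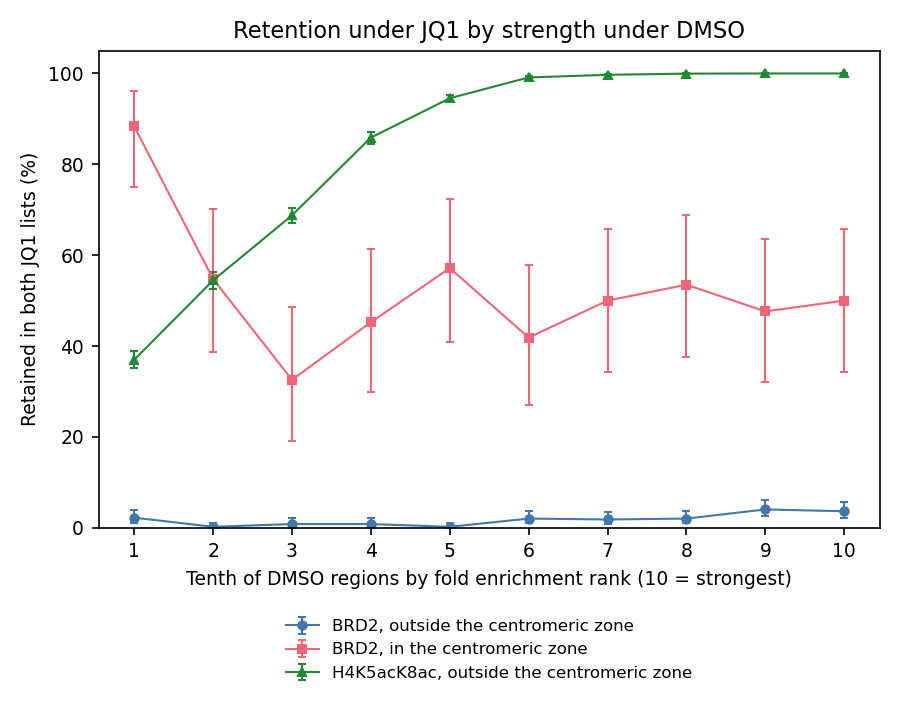
Share of reproducible DMSO regions retained in both JQ1 lists (percent, y axis) in 10 equal classes of fold enrichment rank (x axis, 10 strongest), with exact 95% intervals, for BRD2 outside and inside the centromeric zone and H4K5acK8ac outside it. Ranks were classed within each set of regions. BRD2 outside the zone lies between 0.201% and 4.02% in every class, BRD2 in the zone is highest in the weakest class (88.4%), and H4K5acK8ac runs from 37.0% in the weakest to 100% in the strongest class.

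The second comparison asked whether H4K5acK8ac differed between JQ1 and DMSO. Most acetylated regions were called under both treatments: of 28374 reproducible DMSO regions, 23795 were retained (83.9%, 83.4 to 84.3), 2491 were found in 1 JQ1 list and 2088 were lost (7.36%, 7.06 to 7.67). Shuffled regions gave 4.43%. Peaks numbered 32962 ± 986 (SD, n = 2) under DMSO and 28770 ± 1886 (SD, n = 2) under JQ1, a log2 ratio of −0.20 (exact permutation test, p = 0.333, the smallest possible). They covered 67.2 ± 0.198 Mb under DMSO and 63.6 ± 8.21 Mb under JQ1, a log2 ratio of −0.08 that was smaller than the spread between the JQ1 replicates (exact permutation test, p = 1). JQ1 replicate 1 covered 57.8 Mb and JQ1 replicate 2 covered 69.4 Mb, and without replicate 1 the log2 ratio was 0.046. Only 393 of 25062 reproducible JQ1 regions were gained (1.57%, 1.42 to 1.73). The retained share was 81.9% inside the centromeric zone and 83.9% outside (Fisher's exact test, p = 0.0867).

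Lost H4K5acK8ac regions were weak and narrow under DMSO. Their median percentile was 18.6 against 63.4 for retained regions (permutation test, p = 1e-05, the smallest possible), and their median width was 702 bp against 1735 bp. The strongest retained region spanned chromosome X, 114959377 to 115005864 (Xq23), with fold enrichments of 57.6 and 77.7, and was overlapped by the BRD2 lists of both treatments. It was followed by chromosome 17, 28993686 to 28996546 (17q11.2; 42.3 and 50.5), chromosome 17, 30409934 to 30412805 (17q11.2; 41.1 and 50.9), chromosome 19, 14357997 to 14361008 (19p13.12; 37.9 and 47.8) and chromosome 22, 38612768 to 38617091 (22q13.1; 33.3 and 46.0). The strongest lost region, at chromosome X, 100309760 to 100313929 (Xq22.1), had fold enrichments of only 8.18 and 13.8, and the other four lay in 11q24.1, 18q21.1, 9q13 and 19q13.2. The strongest gained region, at chromosome 21, 44568054 to 44568656 (21q22.3), had 8.54 and 9.77 under JQ1, and the other four lay in 19p13.3, 2q33.1, 10q24.33 and 4p16.3.

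The third comparison set the acetylation mark against BRD2. Under DMSO, 5240 of 5394 BRD2 regions overlapped a reproducible H4K5acK8ac region (97.1%, 96.7 to 97.6), against 3.50% of shuffled regions. Where BRD2 was lost, the mark was still called: 5071 of 5077 lost BRD2 regions lay in H4K5acK8ac under DMSO (99.9%) and 5072 under JQ1 (99.9%). All 5071 were still in H4K5acK8ac under JQ1 (100%, 99.9 to 100). Retained BRD2 regions lay in the mark less often, with 165 of 309 under DMSO (53.4%) and 92 under JQ1 (29.8%). The difference between lost and retained regions was 46.5 percentage points under DMSO (Fisher's exact test, p = 5.22e-186) and 70.1 under JQ1 (p at the written floor of 1e-300). With the mark required in either DMSO replicate, the difference under DMSO was 18.7 points.

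**Figure D4:**
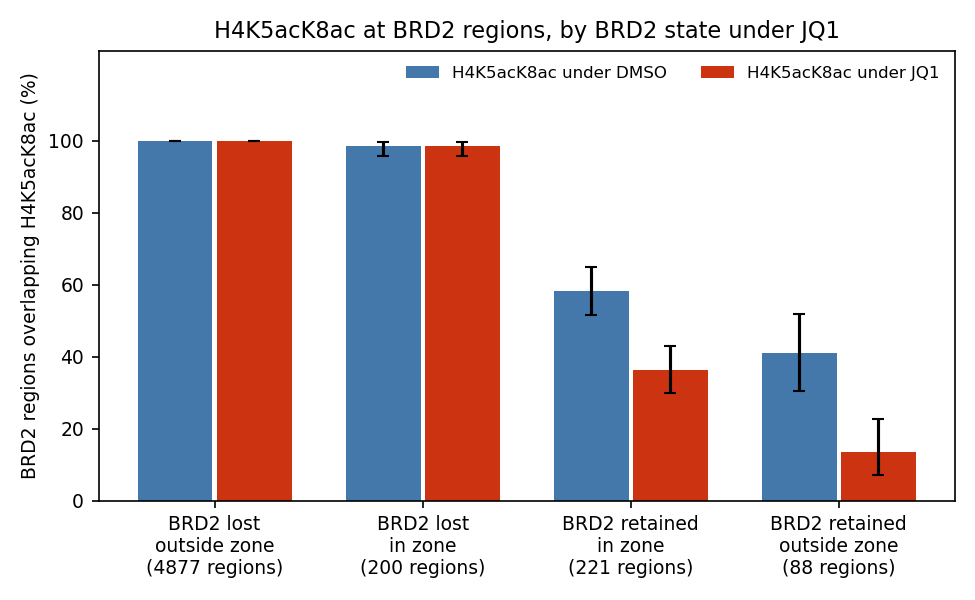
Share of BRD2 regions that overlap a reproducible H4K5acK8ac region (percent, y axis) under DMSO and JQ1, for BRD2 regions lost or retained under JQ1, inside and outside the centromeric zone, with exact 95% intervals. Lost BRD2 regions lie at 98.5% or above under both treatments, and retained regions outside the zone at 40.9% under DMSO and 13.6% under JQ1.

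Outside the zone, BRD2 regions that overlapped no reproducible H4K5acK8ac region under DMSO were retained more often than those that did. Of 56 such regions, 52 were retained (92.9%, 82.7 to 98.0), against 36 of 4914 regions in H4K5acK8ac (0.733%, 0.514 to 1.01; Fisher's exact test, p = 1.43e-94). Inside the zone the shares were 92 of 98 (93.9%) and 129 of 326 (39.6%; Fisher's exact test, p = 7.59e-24). Many of the regions counted as without the mark carried it in 1 DMSO list. With a call in either list counted as the mark, 13 regions outside the zone were without it and 10 were retained, while 78 of the 88 retained regions carried it (1.57% of 4957; Fisher's exact test, p = 4.92e-16). Without BRD2 DMSO replicate 2, every peak of BRD2 DMSO replicate 1 counted as a region, also those found in that list alone. Of 168 regions then without the mark outside the zone, 76 were retained (45.2%). The differences in retention were 44.6 points outside the zone and 33.3 inside.

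H4K5acK8ac regions that held BRD2 under DMSO made up 16.4% of the mark and were its wider and stronger part, with a median width of 2132 bp against 1429 bp and a median percentile of 89.1 against 49.2 (permutation tests, p = 1e-05 each, the smallest possible). All 4540 regions that held a lost BRD2 region were retained under JQ1 (100%, 99.9 to 100), compared with 19206 of 23726 regions without BRD2 (80.9%; Fisher's exact test, p at the written floor of 1e-300) and 47 of 106 regions with a retained BRD2 region (44.3%). Unlike other regions with BRD2, these 106 were narrow and weak, with a median width of 779.5 bp and a median percentile of 35.3. Of them, 72 lay in the centromeric zone. Their retention was not compared at matched width or strength. The difference of 19.1 percentage points between regions with lost BRD2 and without BRD2 was 30.3 without H4K5acK8ac DMSO replicate 1 and 11.3 without H4K5acK8ac JQ1 replicate 1. Within width quintiles the regions without BRD2 were retained at 57.4%, 80.6%, 89.1%, 90.5% and 94.9% from narrowest to widest, each below the 100% of those with lost BRD2 (Fisher's exact test, largest adjusted p = 1.50e-05). Regions with lost BRD2 were unevenly spread over strength quintiles, with 3, 12, 141, 1121 and 3263 regions from weakest to strongest, all retained. Regions without BRD2 were retained at 45.7%, 77.3%, 96.9%, 99.8% and 100% (Fisher's exact test, unadjusted p = 0.0953, 0.0804, 0.0225, 0.227 and 1). The mark covered 14.9 ± 0.778 Mb under DMSO and 15.995 ± 0.653 Mb under JQ1 in regions with BRD2 (SD, n = 2; log2 ratio 0.10, exact permutation test, p = 0.333), and 52.3 ± 0.580 Mb and 47.6 ± 7.56 Mb in regions without (SD, n = 2; log2 ratio −0.14, exact permutation test, p = 1).

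The lists of each antibody were also compared by their Jaccard index, the shared bases over all bases covered. For BRD2 it was 0.540 between the DMSO replicates, 0.748 between the JQ1 replicates and 0.0665 ± 0.0083 (SD over 4 pairs) across treatments. The covered lengths alone kept the BRD2 values across treatments at or below 0.0689 to 0.0855 per pair, so they mainly restate the difference in length. By peaks, 55.0% to 85.3% of the shorter BRD2 list was overlapped across treatments, against 75.2% between the DMSO replicates and 92.6% between the JQ1 replicates. For H4K5acK8ac the Jaccard values were 0.747, 0.732 and 0.681 ± 0.0227. The log2 ratio of peak numbers was 2.12 lower for BRD2 than for H4K5acK8ac. The exact permutation of treatments within each antibody gave p = 0.333 over 36 assignments. The smallest possible value, 0.0556, needs the 2 antibodies to move in opposite directions. For both antibodies each JQ1 list held fewer peaks than each DMSO list. The test could therefore not decide whether the antibodies differed, however large the loss of BRD2 peaks.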

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

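The alternatives for BRD2 by zone and by acetylation and for H4K5acK8ac at lost BRD2 regions under JQ1, restriction to regions outside the centromeric zone, a −log10 p of at least 20 and BRD2 peaks of at least 210 bp were chosen after the data were examined. Over 18 results, 142 of 167 alternatives kept the direction and the side of the threshold or stayed within the replicate spread, but with 2 samples per group no test of numbers or lengths could pass. BRD2 retention (5.73%) was 1.77% outside the zone, 7.86% at −log10 p of at least 20, 0.760% at 50% overlap, 9.39% with matched numbers of peaks and 1.33% for peaks of at least 210 bp. H4K5acK8ac retention (83.9%) was 86.9% at fold 5, 69.1% at −log10 p of at least 20, 72.8% at 50% overlap, 92.6% with either JQ1 list, 90.6% with matched numbers, and 73.7% to 90.5% without 1 replicate. H4K5acK8ac at lost BRD2 regions under JQ1 (99.9%) was 96.9% at −log10 p of at least 20, and 98.0% to 99.9% without 1 replicate. The BRD2 strength difference (4.57) was 0 without BRD2 DMSO replicate 1, 14.2 without BRD2 DMSO replicate 2, 14.1 by −log10 p and 20.6 outside the zone with ranks taken among those peaks alone. The difference in H4K5acK8ac between lost and retained BRD2 regions (46.5 points) ranged from 18.7, with the mark in either replicate, to 65.6, at −log10 p of at least 20, and was 31.3 without H4K5acK8ac DMSO replicate 2. The retention difference by BRD2 state (19.1 points) ranged from 11.3, without H4K5acK8ac JQ1 replicate 1, to 31.1, at −log10 p of at least 20. The log2 ratio of H4K5acK8ac length ranged from −0.22 to 0.046 and reversed without H4K5acK8ac JQ1 replicate 1. By the share of the shorter list overlapped, similarity within minus across treatments was 0.127 for BRD2 (0.578 by Jaccard, 0.464 with matched numbers) and −0.0020 for H4K5acK8ac (0.0591 by Jaccard), a reversal. The log2 ratio of BRD2 peak numbers inside the zone (0.97) turned to −1.05 for peaks of at least 210 bp and −0.40 after merging within 1 kb. The zone contrast in BRD2 retention (50.4 points) was 8.90 at 50% overlap and 15.1 for peaks of at least 210 bp. For BRD2 both settings act through peak width, which differed between the groups, so their values show neither stability nor dependence. The contrast by acetylation outside the zone (92.1 points) was 75.4 with the mark in either replicate and 44.6 without BRD2 DMSO replicate 2. Values without 1 replicate also drop the demand that both lists of its group agree. Other causes were not tested.

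The log2 ratio of BRD2 peak numbers (−2.32) was −4.82 outside the zone, −4.52 for peaks of at least 210 bp, −3.69 after merging within 1 kb and −1.28 at −log10 p of at least 20. Replicate numbers were shared by label only. With the replicate number as a block, log2 ratios were −2.32 and −3.70 for BRD2 number and length, −0.20 and −0.09 for H4K5acK8ac, and −2.13 for their difference in number, and retention was 5.81% and 81.3%. A −log10 p of at least 6 removed no peak, so those alternatives, counted among the 142, test nothing. The same holds where the replicate left out did not enter the result. This was so for H4K5acK8ac at BRD2 regions under DMSO without either H4K5acK8ac JQ1 replicate. It was also so for H4K5acK8ac at lost BRD2 regions under JQ1 without either H4K5acK8ac DMSO replicate. Promoter share and gene lists, with their alternatives, were not run, since no hg19 annotation was used here. Unknown depth leaves open how far uncalled peaks had lost signal.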

Other observations

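All band, staining and domain values here, and the tests of centromeric signal and of acetylation at lost BRD2 sites, were chosen after the result was seen. Of 494 chromosome bands tested (Benjamini-Hochberg adjustment), 10 lay below the rest in H4K5acK8ac retention and 3 above. For 8 of these 10 and 2 of these 3, the exact 95% interval held the retention expected from the strength of the band's regions alone, so that most of these bands did not stand apart from their strength. The lowest was 2p12, with 9 of 20 regions retained (45.0%, Fisher's exact test, adjusted p = 0.0095), with an interval of 23.1% to 68.5% that holds its expectation of 63.3%. Band 3q28 held no reproducible BRD2 region and kept 26 of 50 acetylated regions (52.0%, Fisher's exact test, adjusted p = 7.26e-05), with an interval of 37.4% to 66.3% below its expectation of 74.2%. Band 11p13 kept 52 of 77 (67.5%), with an interval of 55.9% to 77.8% that also lay below its expectation of 80.1%. In 7q21.11, 62 of 90 were kept (68.9%), close to its expectation of 70.0%. Bands 1q21.2 (98.7%), 19q13.33 (92.4%) and 19p13.2 (91.8%) lay above the rest, the last with an expectation of 92.0%. Of these, only 1q21.2 had an interval (92.886% to 99.967%) above its expectation (91.964%). The band intervals were not adjusted, and the bands had been picked by the same retention. An interval that misses its expectation may therefore reflect that choice alone. Among 446 bands tested for gained acetylation, 2q31.2 stood out, with 5 of 27 JQ1 regions gained (18.5%, Fisher's exact test, adjusted p = 0.025). Gained H4K5acK8ac regions were weak, at a median percentile of 15.9 under JQ1 against 56.6 for the others. The share in 2q31.2 was not compared with an expectation from strength.

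By Giemsa staining, the light bands held 2.59 reproducible BRD2 regions per Mb and the darkest bands 0.439 under DMSO. H4K5acK8ac regions were retained in 84.9% of cases in light bands and 75.9% in the darkest (Fisher's exact test, p = 1.30e-21), where strength alone gave 84.9% and 78.5%. At chromosome 18, 3579318 to 3673357 (18p11.31), where all 10 BRD2 regions were lost, the acetylated peaks spanned 94.0 and 93.8 kb under DMSO and 94.2 and 92.5 kb under JQ1. The widest single peak lay at chromosome 15, 67324999 to 67491429 (15q22.33), where JQ1 replicate 2 had 1 peak of 166 kb. The other lists split the same stretch into 12 and 7 peaks under DMSO and 7 in JQ1 replicate 1, and it held no reproducible BRD2 region.

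Outside the centromeric zone, 3.62% of the strongest 10% of BRD2 regions were retained (upper bound 5.66%). A loss of sensitivity that spares the strongest peaks needed over 20%. Arguing against that explanation needed an upper bound below 5%, which was narrowly not met. This bound was written after the zone and the overall overlaps were known but before this retention was computed. Retained regions outside the zone also ranked higher under DMSO than lost ones (median percentile 76.8 against 56.6). The retention thus fell short of what the explanation needed, without excluding it. BRD2 libraries without enrichment under JQ1 remain open: retention was 1.56% in the other regions (Fisher's exact test against the strongest, p = 0.0032), but a failed immunoprecipitation and full displacement of BRD2 by JQ1 predict nearly the same lists and cannot be told apart without read counts or spike-in counts. The narrowest peaks, 48 bp under JQ1 against 196 and 209 bp under DMSO, show that the shortest width called differed between the BRD2 groups. Displacement of BRD2 by JQ1 was therefore not tested apart from this.

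The residual BRD2 peaks beside centromeres may be repeat signal that is present with and without JQ1, but this was not decided. Of the reproducible JQ1 regions of the zone, 67.9% overlapped both DMSO lists, by at least 1 bp, against 58.7% outside the zone. BRD2 that stayed bound would give the same overlap, and repeats were not examined, so the share cannot tell these apart. Many JQ1 regions were pieces of one DMSO region: 746 lay in 221 retained zone regions, with up to 46 in a single region. A move of BRD2 to centromeric chromatin under JQ1 is not decided. The covered length of the zone under JQ1 was 0.484 of that under DMSO, but the narrowest callable width differed between the lists, so that this test is void.

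The H4K5acK8ac regions lost under JQ1 were weak ones, at a median percentile of 18.6, in line with regions near the calling threshold dropping out. Of the 2088 lost regions, 1 (0.0479%, upper bound 0.267%) held a BRD2 peak of either DMSO list that was absent from both JQ1 lists. This argues only against the loss of called BRD2 peaks inside these regions as the source of their loss. Loss of called BRD2 peaks elsewhere was not examined as a source. Few regions this weak could enter that share: the weakest 2 strength quintiles held 3 and 12 regions with lost BRD2, against 5626 and 5641 without BRD2. Loss of BRD2 too weak to be called was not tested. A fall in acetylation signal at lost BRD2 sites stays open, since the acetylated regions at those sites were strong and could still be called. Lost regions are by definition absent from both JQ1 lists, so fewer calls in JQ1 replicate 1 alone cannot produce them, and 16.8% of DMSO peaks were missing from JQ1 replicate 2, against 12.1% from the other DMSO list. Between the JQ1 replicates, 5.93% of replicate 1 peaks and 16.1% of replicate 2 peaks were missing from the other list. A share of this size thus also occurred between replicates of 1 treatment. Whether the weak regions lost signal under JQ1 or were called differently was not tested.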
